A study of Homo sapiens with 12 samples.

How the data were processed

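Total RNA of Caco-2 cells was profiled on 12 Illumina HumanHT-12 V4 bead arrays, each hybridised with 1 biotin-labelled sample. The 4 groups of 3 arrays combine 2 siRNAs (a non-targeting control, or siRNA against the metal-responsive transcription factor MTF1) with 2 zinc concentrations (3 or 150 µM). Per the labels' protocols, cells were transfected with lipofectamine RNAiMAX, RNA was extracted with Trizol and checked for integrity, and 200 ng was amplified and labelled. The duration of the zinc treatment and of the knockdown is not given in the sources used here. Groups and replicate numbers came from the sample titles. The series design text speaks of a knockdown of ZNF658 with 2 siRNAs, whereas the series title and all 12 sample labels name MTF1. The sample labels were followed.

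The deposited table of the whole series held bead-summarized probe intensities on a linear scale, not normalized per the file headers, and beside each a detection p-value per the file headers, which sets the probe's signal against negative controls. The scanner software and bead summarization are not given in the sources used here. A further deposited table, the series matrix, held the authors' processed log2 values of the same arrays. Its 12 array medians were 7.03 to 2 decimals, its ranks were those of the raw intensities, and its dim probes were not background-subtracted. Its scale, centring and direction were therefore settled from the values. No saturation mark comes with the files, so probes at the top of the range were not treated apart.

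Intensities were background-corrected by normexp, with the background taken from the detection p-values, an offset of 16 was added, and arrays were quantile normalized and brought to log2 (the function neqc of limma 3.58.1, R 4.3.3). Of 47323 probes, 30113 carry 1 gene symbol in the platform annotation, 8 carry several and 17202 carry none there. Symbols were updated through the gene identifier, which matched 30074 probes. A probe entered the tests if its detection p-value was under 0.05 on all 3 arrays of at least 1 group, which 17413 probes met. Each gene was represented by its entering probe of highest mean, and the 3701 entering probes without a single symbol were tested as themselves and left unnamed. This gave 14285 features, of which 10584 were named genes. Both groups of features are called genes in counts.

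A linear model with 1 mean per group was fitted to all 12 arrays with limma (lmFit and eBayes). The comparisons were zinc with control siRNA, zinc with MTF1 siRNA, MTF1 siRNA at low zinc, MTF1 siRNA at high zinc, and the difference between the zinc responses (the interaction). P-values were adjusted by the Benjamini-Hochberg method over the 14285 features of each comparison, with 0.05 as the threshold. All p-values are two-sided and all adjusted p-values of genes are limma's. A log2 change is given with its standard error (SE) from the fit. Where all 3 arrays of a group were not above background, the fold is a bound, written as at least N-fold. It sets the brighter group's mean against, per array, the higher of the lowest signal among detected probes and the dim probe's own signal. Levels of different probes were compared only to choose each gene's probe, to set these bounds and to sort probes by brightness.

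The genes named were chosen by rule. For each comparison they were up to 12 genes that rose most and 12 that fell most among named genes past the threshold, with the 3 arrays of the groups compared not overlapping. That last condition was not used for the interaction. MTF1, ZNF658, the metallothioneins, SLC30A1 and SLC39A10 were always included, as were members past the threshold of a described gene list. Where fewer than 5 genes passed, the 5 of smallest p-value were taken. The 32 gene lists covered zinc, iron and copper handling, stress responses, signalling, metabolism, the cell cycle and markers of intestinal and other cell types. Each list was tested with camera at a preset correlation of 0.01, adjusted over the 32 lists of a comparison. Camera with a correlation estimated from the data, and fry, were run beside it. Counts of members past the threshold are given over all genes and adjusted over the list alone.

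These groups, comparisons, lists and naming rules, and the alternatives tried, were fixed before the data were examined. The alternatives were no background correction, centring each array on its median, the authors' log2 values, no filter or a stricter filter on dim probes, all entering probes, the replicate number as a block, only the 2 groups compared, a mean-variance trend with robust eBayes, array weights, and each array left out in turn. The tests were checked on simulated data with the spread of these arrays and 14285 genes, each drawn independently of the others. For the comparison of siRNAs at low zinc, 31 of 67 genes changed 1.5-fold were recovered, 54 of 67 changed 2-fold and 66 of 66 changed 4-fold, with 5 unchanged genes called. For the interaction, 11 of 67, 30 of 67 and 63 of 66 were recovered, with 5 unchanged genes called. A simulated list of 20 genes moved 1.5-fold had a camera p-value of 2.17e-42, or 3.99e-07 with an estimated correlation. Of 200 unchanged lists, 8 and 6 had a p-value under 0.05. With no correlation between simulated genes, this cannot show how the preset correlation holds for the real lists.

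Between 18191 and 19469 probes per array (38.4% to 41.1%) were detected, and median intensities lay between 121.6 and 134.8. Within groups, log2 values of 2 arrays correlated at 0.989 to 0.992. No 2 arrays were alike enough to be counted as 1. The number of arrays, 3 per group, limits the precision. Nothing in the labels says that the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.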

Results

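Gene expression was measured in Caco-2 cells, an established epithelial line from a human colonic adenocarcinoma, after transfection with siRNA against MTF1 or a non-targeting control and exposure to 3 µM (low) or 150 µM (high) zinc. MTF1 is a zinc-finger transcription factor that senses zinc and activates metallothionein genes. The series title sets out to learn how MTF1 shapes the transcript response to zinc. Each of the 4 groups held 3 arrays, and 18191 to 19469 of the 47323 probes were detected per array. Values are normalized log2 intensities, and a group's level is its mean ± SD over 3 arrays.

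The targeted gene was lower on every MTF1 siRNA array than on every control array at the same zinc concentration. MTF1 stood at 6.61 ± 0.15 with control siRNA and 5.90 ± 0.33 with MTF1 siRNA at low zinc, and at 6.70 ± 0.13 and 5.72 ± 0.48 at high zinc (SD, n = 3). Chance alone separates 3 arrays from 3 in this way in 10% of cases, counting both directions. The difference at low zinc was -0.71 ± 0.22 (SE) and did not pass (limma, adjusted p = 0.201). At high zinc it was -0.98 ± 0.22, a 1.97-fold lower level (adjusted p = 0.0483). That call was kept without MTF1 siRNA low-zinc replicate 1 or high-zinc replicate 2 and lost without each of the other 10 arrays in turn, where adjusted p ran from 0.0574 to 0.141, and with the replicate block (adjusted p = 0.0825), only the 2 groups compared (0.0984) or no filter on dim probes (0.129). Zinc did not move MTF1 past the threshold with either siRNA (0.09 with adjusted p = 0.812, and -0.17 with adjusted p = 0.662). The 2 probes of ZNF658, the zinc-linked repressor named in the series design text, were not above background on any array.

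High against low zinc with control siRNA asks which transcripts respond to zinc. Metallothioneins, small cysteine-rich proteins that bind zinc and copper, rose, and all 8 measured members passed. MT1M rose by 6.32 ± 0.16 (SE) from 5.09 ± 0.20 to 11.41 ± 0.30 (SD, n = 3; limma, adjusted p = 5.15e-10), but was detected on 1 of 3 low-zinc arrays, so the size of the rise rests in part on the background floor. MT1B was not above background at low zinc and rose at least 44.2-fold (adjusted p = 1.36e-10). The log2 changes of MT1H, MT1E, MT1G, MT1X, MT2A and MT1F lay between 3.84 for MT1F and 5.59 for MT1H. Probes of these near-identical genes may cross-hybridise. A second MT1H probe was above background on 4 of the 12 arrays only. The list passed (camera, adjusted p = 5.15e-18, or 0.0228 with an estimated correlation), with 8 of 8 also when adjusted over the list alone. Beside them rose SNORD3C (4.19) and SNORD3D (4.07), copies of the U3 small nucleolar RNA that takes part in ribosomal RNA processing.

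Zinc transporters moved in opposite directions with control siRNA. SLC30A1 (ZnT1), which exports zinc across the plasma membrane, rose 6.24-fold from 8.67 ± 0.08 to 11.31 ± 0.12 (SD, n = 3; limma, adjusted p = 1.44e-08). SLC30A2 (ZnT2), which loads zinc into vesicles, rose by 4.62 ± 0.21 and was detected on 1 of 3 low-zinc arrays (adjusted p = 5e-08). SLC39A10 (ZIP10), a zinc importer, fell by 1.86 ± 0.17 (adjusted p = 2.68e-05). Of the 7 SLC30 exporters measured, 3 rose, the third being SLC30A5 (0.36), whose call was lost without some arrays, and 4 rose when adjusted over the list alone (camera, adjusted p = 3.31e-04). That call was lost with an estimated correlation (adjusted p = 0.116). Of 10 SLC39 importers 4 fell, also when adjusted over the list alone, where 1 rose, and this list did not pass (adjusted p = 0.135).

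**Figure D1:**
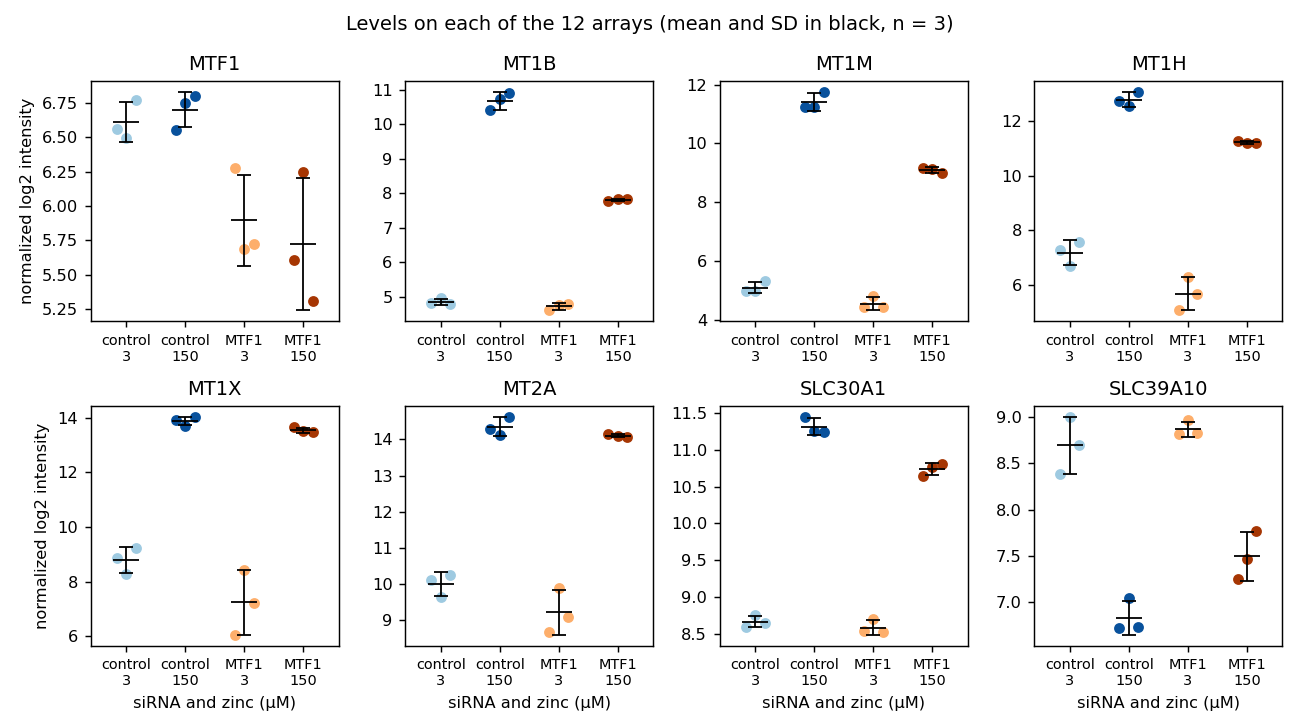
Normalized log2 intensity of 8 genes on each of the 12 arrays, by siRNA (control or MTF1) and zinc (3 or 150 µM); points are arrays, black bars are the mean and SD of 3 arrays, and each panel has its own vertical axis. MTF1 is lower with its siRNA at both zinc concentrations, MT1B and MT1M at high zinc stand lower with MTF1 siRNA (7.81 and 9.10 against 10.68 and 11.41), and SLC39A10 falls with zinc under both siRNAs.

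Heat shock genes rose with zinc under control siRNA: 14 of 23 measured members rose and none fell (17 and 0 adjusted over the list alone; camera, adjusted p = 2.69e-12, or 0.00405 with an estimated correlation). HSPA6, an HSP70 chaperone made under stress, rose by 5.02 ± 0.16 (limma, adjusted p = 3.55e-09). HSPA1A rose by 2.46, the small chaperone CRYAB by 1.86, HSPA1B by 1.59, the co-chaperone BAG3 by 1.31 and DNAJB1 by 1.14. Probes of HSPA1A and HSPA1B may read both near-identical genes. HSPA4 rose by 0.91, but its second probe changed by -0.07 (adjusted p = 0.730).

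Immediate early genes, transcription factors and feedback regulators induced within minutes of a stimulus, rose too: 15 of 20 rose and none fell (15 and 0 adjusted over the list alone; camera, adjusted p = 5.94e-15, or 6.45e-04 with an estimated correlation). The AP-1 subunits FOS, FOSB and JUN rose by 2.62 ± 0.11, 1.87 ± 0.11 and 1.42 ± 0.13 (SE; limma, highest adjusted p = 2.81e-05). CCN2, a matricellular growth factor, rose by 1.82 and the phosphatase DUSP1 by 1.49. In the list of the unfolded protein and ATF4 response, 14 of 24 members rose (15 up and 2 down adjusted over the list alone; camera, adjusted p = 3.02e-08, or 0.00514 with an estimated correlation). They included the mTORC1 inhibitor DDIT4 (1.82), the stress factor ATF3 (1.52), PPP1R15A, which restores translation after stress (1.28), and the pro-apoptotic factor DDIT3 (0.82). In the list of targets of NRF2, the oxidative stress factor, 12 of 22 rose (13 adjusted over the list alone; camera, adjusted p = 1.05e-06, or 0.0113 with an estimated correlation). The cystine importer SLC7A11 rose at least 2.14-fold, haem oxygenase HMOX1 by 1.09, sulfiredoxin SRXN1 by 0.88 and thioredoxin reductase TXNRD1 by 0.78. GCLM, a subunit of the enzyme that limits glutathione synthesis, rose by 0.76 on its main probe and changed by 0.05 on a second.

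Genes of the differentiated enterocyte fell with zinc under control siRNA. Of 14 measured, 8 fell and 1 rose (9 and 1 adjusted over the list alone; camera, adjusted p = 1.36e-04, or 0.0148 with an estimated correlation). APOC3 and APOB, lipoprotein proteins, fell by 1.48 ± 0.23 and 1.02 ± 0.09 (SE), the chloride exchanger SLC26A3 fell by 1.38 and sucrase-isomaltase (SI) fell by 1.22 (limma, highest adjusted p = 0.0124, for SI). The adhesion molecule CEACAM1 rose by 0.74. Among the genes that fell most were GSTA2, a glutathione transferase (-1.90), TFF3, a peptide of mucus-secreting cells (-1.77), the phosphatase ACP3 (-1.70), the retinol carrier RBP2 (-1.67) and TMEM8B (-1.65). HSD17B2, which inactivates sex steroids (-1.64), CPS1, which makes carbamoyl phosphate for the urea cycle (-1.63), SLC23A3 (-1.60), the chemokine CXCL12 (-1.58), the plasmin inhibitor SERPINF2 (-1.53) and the sulfotransferase SULT2A1 (-1.49) followed. Their limma adjusted p-values ran up to 2.17e-04 for ACP3.

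Further lists passed at the preset correlation with control siRNA. Mitotic genes rose in 11 of 28 (12 adjusted over the list alone; camera, adjusted p = 1.03e-05, or 0.0246 with an estimated correlation), among them cyclin CCNA2 (0.60) and the centromere histone CENPA (0.55). Of the mesenchymal and fibroblast markers, 4 rose and 1 fell out of 11, with the same counts adjusted over the list alone (camera, adjusted p = 0.00784, or 0.0570 with an estimated correlation). The largest were the contractile genes ACTA2 (1.76) and TAGLN (1.61). Respiratory chain genes fell in 10 of 25 (14 adjusted over the list alone; adjusted p = 4.03e-05, or 0.0839 with an estimated correlation), led by the complex I subunit NDUFB7 (-0.97). In the hypoxia and glycolysis list, 9 rose and 2 fell out of 22 (12 and 2 adjusted over the list alone; adjusted p = 1.36e-04, or 0.116 with an estimated correlation), led by the vasodilator peptide ADM (1.86) and the histone demethylase KDM3A (1.14). DNA replication genes rose in 6 of 23, also adjusted over the list alone (adjusted p = 0.00289, or 0.194 with an estimated correlation), the replication licensing factor CDC6 by 0.52. Inflammation genes rose in 4 of 15 (6 adjusted over the list alone; adjusted p = 0.0242, or 0.158 with an estimated correlation), the cytokine IL32 by 0.93. Fatty acid synthesis genes fell in 6 of 15 (7 down and 1 up adjusted over the list alone; adjusted p = 0.0148, or 0.104 with an estimated correlation), with the triglyceride enzyme DGAT1 at -0.94 and the desaturase FADS1 at -0.75. Fatty acid oxidation genes fell in 3 of 13, also adjusted over the list alone (adjusted p = 0.0256, or 0.0922 with an estimated correlation), the thioesterase ACOT1 at -0.95.

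In all, limma called 2573 of 14285 genes changed by zinc with control siRNA, 1232 higher and 1341 lower, and 1219 of them by at least 1.5-fold. With arrays centred on their median the balance turned, to 1259 higher and 1017 lower. The 25 called genes that the naming rule chose for this comparison kept their calls under every alternative that gave them a value and without any 1 array. Of the 117 calls of list members, 73 did. The count fell to 1540 with no filter on dim probes, to 1607 without control low-zinc replicate 1 and to 1682 without control high-zinc replicate 3.

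Zinc with MTF1 siRNA asks how the response runs once MTF1 is targeted. Metallothioneins rose here too and all 8 passed (camera, adjusted p = 6.91e-19, or 0.0209 with an estimated correlation; 8 of 8 adjusted over the list alone). MT1X rose by 6.30 ± 0.44 (SE) from 7.24 ± 1.19 to 13.55 ± 0.09 (SD, n = 3; limma, adjusted p = 1.82e-06), MT1G by 5.71, MT1E by 5.65, MT1H by 5.53, MT2A by 4.90 and MT1F by 4.06. SNORD3C (4.66), SNORD3D (4.30), SNORD3A (4.05) and RPPH1, the RNA of RNase P (3.82), also rose. MT1M and MT1B were not above background at low zinc and rose at least 14.8-fold and 6.08-fold (adjusted p = 1.1e-08 and 1.59e-08). SLC30A1 rose 4.43-fold, from 8.59 ± 0.10 to 10.74 ± 0.09 (SD, n = 3; limma, adjusted p = 4.48e-08). SLC30A2 rose at least 7.34-fold, while its second probe, above background on 1 of the 6 arrays compared, did not pass (adjusted p = 0.286). SLC39A10 fell by 1.38 ± 0.17 (adjusted p = 2.06e-04).

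Of the SLC30 exporters, 2 of 7 rose with MTF1 siRNA, also adjusted over the list alone (camera, adjusted p = 0.00678, or 0.204 with an estimated correlation). Of the SLC39 importers, 4 of 10 fell, also adjusted over the list alone (adjusted p = 0.0123, or 0.0731 with an estimated correlation), SLC39A8, which also carries manganese, at -1.13. HSPA6 was not above background at low zinc and rose at least 43.9-fold (limma, adjusted p = 1.77e-09). In the heat shock list 10 of 23 rose, also adjusted over the list alone (camera, adjusted p = 1.52e-09, or 0.00508 with an estimated correlation), CRYAB at least 4.11-fold and HSPA1A by 2.29. Immediate early genes rose in 15 of 20 (17 adjusted over the list alone; adjusted p = 7.69e-20, or 2.08e-04 with an estimated correlation), with FOS at 2.91, FOSB at 2.30, JUN at 2.14 and EGR1, a growth-factor-induced zinc finger, at 1.86. The ATF4 list rose in 15 of 24 (17 adjusted over the list alone; adjusted p = 2.56e-11, or 0.00239 with an estimated correlation), with ATF3 at 1.88, DDIT4 at 1.76, PPP1R15A at 1.64 and DDIT3 at 1.34. NRF2 targets rose in 8 of 22 (11 adjusted over the list alone; adjusted p = 1.41e-05, or 0.0173 with an estimated correlation), with SLC7A11 at least 2.42-fold and HMOX1 at 1.32.

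Enterocyte genes fell in 10 of 14 and 1 rose, with the same counts adjusted over the list alone (camera, adjusted p = 1.56e-06, or 0.00508 with an estimated correlation). MTTP, which loads lipid onto APOB, fell at least 4.45-fold to below background (limma, adjusted p = 8.06e-06), APOB fell by 1.61 ± 0.09 (SE) and SI fell by 1.71 ± 0.28. CEACAM1 rose by 0.85, and its second probe changed by 0.11. CPS1 fell by 2.27 ± 0.10 (adjusted p = 3.06e-08), followed by SULT2A1 (-2.05), GSTA2 (-2.01), HSD17B2, CXCL12 (-1.96) and the cholesterol exporter ABCA1 (-1.93). SERPINF2 (-1.91), the sphingosine phosphate phosphatase SGPP2 (-1.89), RHBDL3 (-1.86) and the uroplakin UPK1A (-1.83) also fell, and SLC23A3 fell at least 2.72-fold. Fatty acid synthesis genes fell in 7 of 15 (10 adjusted over the list alone; camera, adjusted p = 1.22e-04, or 0.0231 with an estimated correlation), GPAM, which starts glycerolipid synthesis, at -0.82. Fatty acid oxidation genes fell in 5 of 13 (8 adjusted over the list alone; adjusted p = 0.00521, or 0.0399 with an estimated correlation). Cholesterol synthesis genes fell in 4 of 18 (5 adjusted over the list alone; adjusted p = 0.0110, or 0.0507 with an estimated correlation), the sterol reductase TM7SF2 at -1.39.

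Mesenchymal and fibroblast markers rose in 3 of 11 with MTF1 siRNA, also adjusted over the list alone (camera, adjusted p = 0.00277, or 0.0311 with an estimated correlation), ACTA2 by 2.07 and TAGLN by 1.86. Hypoxia genes rose in 7 of 22 (9 up and 1 down adjusted over the list alone; adjusted p = 7.62e-05, or 0.0906 with an estimated correlation), ADM by 1.94. Inflammation genes rose in 6 of 15 (6 up and 2 down adjusted over the list alone; adjusted p = 0.00371, or 0.0770 with an estimated correlation), IL32 by 1.30. Mitotic genes rose in 2 of 28, also adjusted over the list alone (adjusted p = 0.00371, or 0.0831 with an estimated correlation), the kinase-binding protein CKS2 by 0.64. Respiratory chain genes fell in 2 of 25, also adjusted over the list alone (adjusted p = 0.0121, or 0.215 with an estimated correlation), the ATP synthase subunit ATP5F1A at -0.48. Of p53 targets, 5 of 14 rose and 1 fell (5 and 2 adjusted over the list alone; adjusted p = 0.0485, or 0.0965 with an estimated correlation and 0.0580 with the replicate block). They included the cell cycle inhibitor CDKN1A (1.43) and the stress cytokine GDF15 (1.08).

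**Figure D2:**
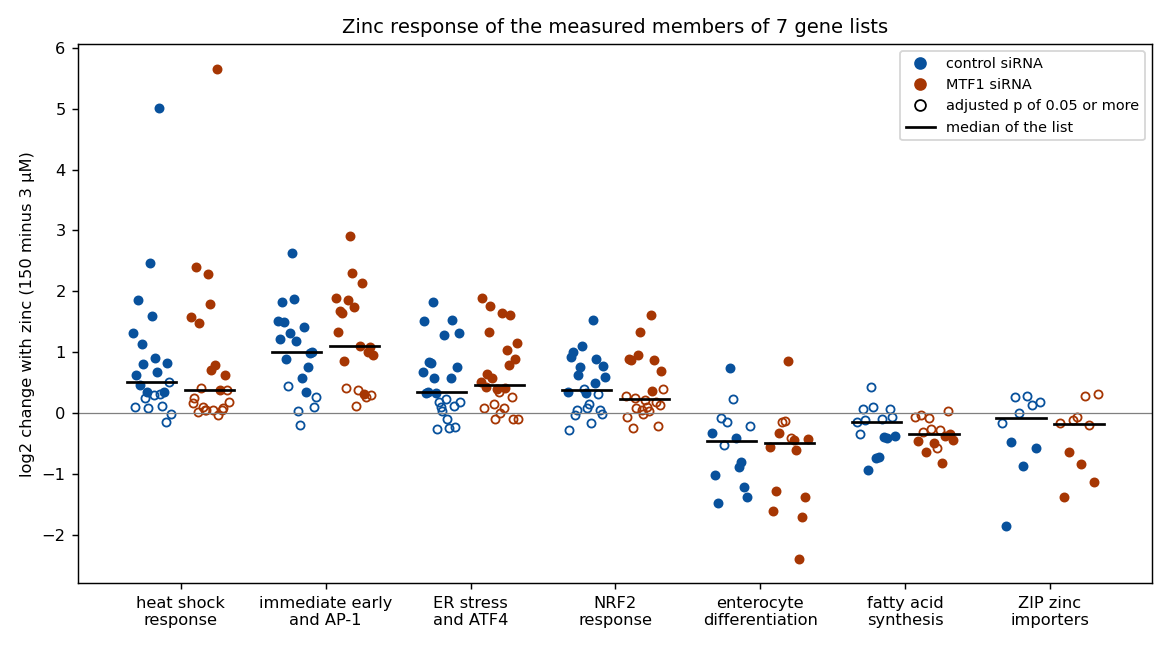
Log2 change with zinc (150 minus 3 µM) of the measured members of 7 gene lists with control siRNA and MTF1 siRNA; filled points passed an adjusted p of 0.05, open points did not, and black lines are medians. Members of the heat shock and immediate early lists lie mostly above 0 (FOS at 2.62 and 2.91), and enterocyte genes mostly below (APOB at -1.02 and -1.61).

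In all, 2244 genes were called with MTF1 siRNA, 1028 higher and 1216 lower, and 1168 of them changed at least 1.5-fold. With arrays centred on their median the balance turned here too, to 1040 higher and 978 lower. The 27 called genes that the naming rule chose for this comparison kept their calls under every alternative that gave them a value and without any 1 array, as did 69 of the 99 calls of list members. No array is common to the 2 zinc comparisons. They shared 569 rises and 560 falls, against 88.7 and 114 for independent lists of those sizes. The excess may come in part from that common spread. Across all genes, which are not independent replicates, the log2 changes correlated at r = 0.680 (Spearman's rho = 0.470). Of the 3680 genes called in either comparison, 86.0% moved the same way in the other, and 8 were called in opposite directions. The lists that passed in neither zinc comparison were other reported MTF1 targets, iron and copper handling, interferon response, intestinal stem cell, goblet cell, immune cell, histones, ribosome biogenesis, proteasome, autophagy, apoptosis, genes linked to ZNF658, RNA interference and housekeeping (adjusted p between 0.0666 and 0.967). SLC39 importers (0.135), p53 targets (0.548) and cholesterol synthesis (0.856) did not pass with control siRNA, nor DNA replication (0.0575) with MTF1 siRNA. A list that passed with 1 siRNA alone is not thereby shown to differ between them.

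**Figure D3:**
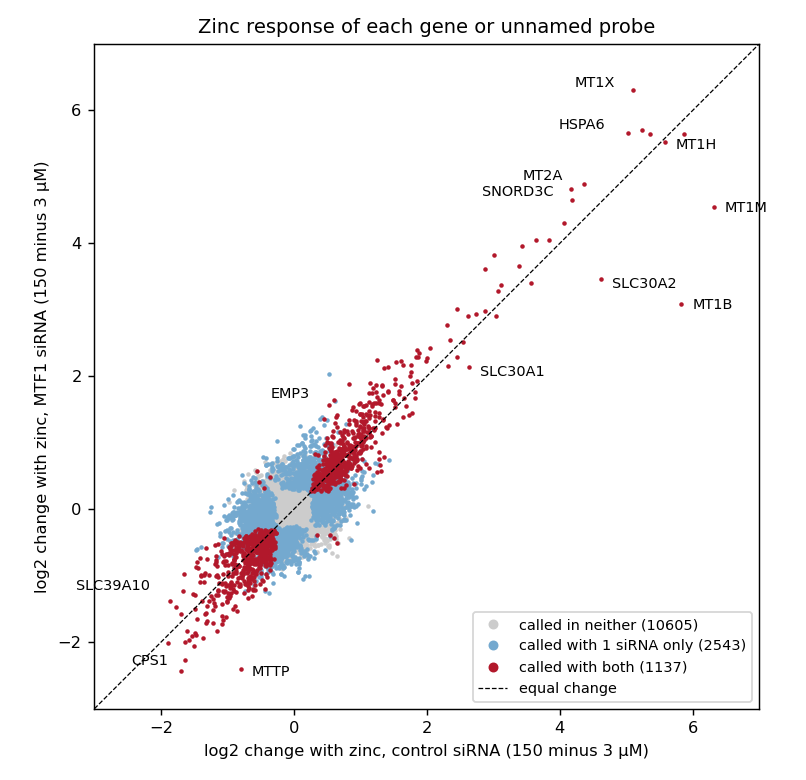
Log2 change with zinc (150 minus 3 µM) of each of 14285 genes or unnamed probes with control siRNA (horizontal) and MTF1 siRNA (vertical); colours mark those past an adjusted p of 0.05 with both siRNAs, with 1, or with neither, and the dashed line is an equal change. MT1B (5.83 and 3.09) and MT1M (6.32 and 4.55), both at or near background at low zinc, lie below the line, and EMP3 (0.53 and 1.57) above it.

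MTF1 siRNA against control at low zinc asks which transcripts differ with MTF1 siRNA when little zinc is added. The estimates for 6 metallothioneins above background were lower with MTF1 siRNA, but none passed over all genes. MT1G differed by -1.80 ± 0.40 (SE; limma, adjusted p = 0.109), MT1X at -1.54 ± 0.44 (0.175), MT1H at -1.49 ± 0.28 (0.0748), MT1F at -1.08 ± 0.21 (0.0823), MT1E at -0.79 ± 0.25 (0.207) and MT2A at -0.78 ± 0.26 (0.228). MT1B was not above background in either group, nor MT1M with MTF1 siRNA, and neither passed. As a list they passed (camera, adjusted p = 1.57e-07), with 7 of 8 lower adjusted over the list alone, and the call was lost with an estimated correlation (adjusted p = 0.527). Their spread was wide. Metallothionein probes took 0.0139% of the corrected signal on MTF1 siRNA replicate 2 and 0.00565% and 0.00720% on the other arrays of that group. The control arrays had 0.0184%, 0.0138% and 0.0200%, so the groups overlapped in this summed share. By single probes, the arrays of the groups overlapped for MT1X, MT2A and MT1E but not for MT1H, MT1F and MT1G. SLC30A1 (-0.08, adjusted p = 0.736) and SLC39A10 (0.18, adjusted p = 0.670) did not pass, and no other list did (adjusted p from 0.128 to 0.956).

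At low zinc 17 genes passed, 5 higher and 12 lower with MTF1 siRNA. ITM2C, a membrane protein of the BRI family, fell by 0.92 ± 0.12 (SE; limma, adjusted p = 0.0168), SMAD5, a transducer of bone morphogenetic protein signals, at -0.70 ± 0.09 (0.0168), and OCRL, a phosphoinositide phosphatase, at -0.69 ± 0.09 (0.0168). The microtubule kinase DCLK1 (-1.01), the ubiquitin-conjugating enzyme UBE2Q1 (-0.74), the forkhead repressor FOXN3 (-0.62), the replication helicase subunit MCM2 (-0.59) and cyclin CCNB2 (-0.55) were also lower, and the pseudogene SSPOP was at least 1.30-fold lower. KIR2DL5B, a receptor gene of natural killer cells, was at least 1.26-fold higher, and EIF3CL, a copy of a translation initiation gene whose probe may read both copies (0.64), KCTD20 (0.61) and STMN3, which binds tubulin (0.60), were higher. None of these 13 named calls held in every alternative and omission. The count was 0 without MTF1 siRNA low-zinc replicate 1, control low-zinc replicate 1 or control low-zinc replicate 3, 1 without MTF1 siRNA low-zinc replicate 3, 3 without control low-zinc replicate 2, and 8 to 11 without any 1 high-zinc array other than control replicate 2. It was 3 with the replicate block and 152 with the authors' log2 values.

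MTF1 siRNA against control at high zinc asks which transcripts differ with MTF1 siRNA at that concentration, whether or not zinc induced them. Only the interaction tests the zinc response. With only MTF1 siRNA and control siRNA compared, a loss of MTF1 cannot be told apart from other effects of that siRNA. Among the metallothioneins and SLC30 exporters, those that fell with MTF1 siRNA were MT1B, by 2.87 ± 0.12 (SE; from 10.68 ± 0.26 to 7.81 ± 0.03, SD, n = 3; limma, adjusted p = 4.88e-07), MT1M, by 2.32 ± 0.16 (adjusted p = 7.33e-05), MT1H, by 1.55 ± 0.28 (adjusted p = 0.0240), SLC30A2, by 1.44 ± 0.21 (adjusted p = 0.0122), and SLC30A1, by 0.57 ± 0.10 (adjusted p = 0.0188). MT1F differed by -0.87 ± 0.21 (adjusted p = 0.0596), MT1G at -1.33 ± 0.40 (0.104), MT1E at -0.50 ± 0.25 (0.276), MT1X at -0.34 ± 0.44 (0.713) and MT2A at -0.25 ± 0.26 (0.624), and these did not pass. Still, the arrays of the groups did not overlap for MT1F, MT1G, MT1E and MT1X, and overlapped for MT2A. The fit shares the spread of all 4 groups. It was widest with MTF1 siRNA at low zinc for MT1G and MT1X (SD 1.10 and 1.19, against 0.05 and 0.09 with MTF1 siRNA at high zinc). SLC39A10 differed by 0.66 ± 0.17 and did not pass (0.0685). As lists, the metallothioneins (3 of 8 fell, 5 adjusted over the list alone; camera, adjusted p = 2.26e-07) and the SLC30 exporters (2 of 7 fell, 4 adjusted over the list alone; adjusted p = 0.0139) passed. Both calls were lost with an estimated correlation (adjusted p = 0.162 and 0.327). Metallothionein probes took 0.292% to 0.317% of the corrected signal with MTF1 siRNA and 0.422% to 0.544% with control siRNA. The call of SLC30A1 was lost with median-centred arrays, with no filter, with only the 2 groups compared and without MTF1 siRNA high-zinc replicate 1, MTF1 siRNA high-zinc replicate 2 or control high-zinc replicate 3, up to an adjusted p of 0.0782.

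Genes outside zinc handling changed too. PERP, a desmosome protein, fell by 1.21 ± 0.15 (SE; limma, adjusted p = 0.00874), VAC14, a scaffold of a phosphoinositide kinase, at -1.31 ± 0.17 (0.00934), SPIRE1, an actin nucleator, at -1.06 ± 0.15 (0.0106) and MTTP at least 1.91-fold (0.0188). TUBE1, a centriole tubulin (-1.18), LONRF1 (-1.15), the cytoskeletal SEPTIN7 (-1.05) and MBLAC2 (at least 1.62-fold) were also lower. EMP3, a membrane glycoprotein, rose by 0.81 ± 0.10 (adjusted p = 0.00664) and the stress factor ATF5 by 0.83 ± 0.14 (0.0177). SPHK1, which makes sphingosine phosphate (1.00), ATXN2L (0.92), the stress-induced SESN2 (0.91), the circadian factor DBP (0.89), ZBTB3 (0.86), the xenobiotic oxidase CYP1A1 (0.85), ZNF593 (0.82), RTL8B (0.81), the RNase P subunit POP7 (0.81) and UBTF, which drives ribosomal RNA transcription (0.80), also rose. Second probes of UBTF (-0.17) and RTL8B (0.17) did not pass.

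Cholesterol synthesis genes stood lower at high zinc with MTF1 siRNA: 2 of 18 fell (8 adjusted over the list alone; camera, adjusted p = 0.00194, or 0.0650 with an estimated correlation), IDI1, which isomerises isoprenoid precursors, at -0.77 and DHCR7, of the last step, at -0.50. Enterocyte genes fell in 2 of 14 (4 adjusted over the list alone; adjusted p = 0.00194, or 0.0650 with an estimated correlation), APOB at -0.60. Histone genes passed as a list upward with 0 of 14 past the threshold (5 adjusted over the list alone; adjusted p = 0.00341, or 0.159 with an estimated correlation). Inflammation genes rose in 1 of 15 (4 adjusted over the list alone; adjusted p = 0.0113, or 0.162 with an estimated correlation), the manganese superoxide dismutase SOD2 by 0.41. Of p53 targets, 2 of 14 rose (5 adjusted over the list alone; adjusted p = 0.0171, or 0.155 with an estimated correlation), CDKN1A by 0.61 and SESN2. Immediate early genes rose in 1 of 20 (5 up and 1 down adjusted over the list alone; adjusted p = 0.0299, or 0.155 with an estimated correlation), ATF3 by 0.40. The other lists did not pass (adjusted p from 0.0751 to 0.945).

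In all, 271 genes were called at high zinc, 96 higher and 175 lower, and 167 changed at least 1.5-fold. With arrays centred on their median the split was 89 higher to 95 lower, and with the authors' log2 values 439 to 503. Of the 26 called genes that the naming rule chose, MT1B, MT1M, EMP3 and PERP kept their calls in every omission and under every alternative that gave them a value; the strict filter gave none for MT1B and MT1M. The count fell to 21 without MTF1 siRNA high-zinc replicate 2, to 39 without replicate 1 and to 98 without replicate 3 of that group, to 70 and 45 without control high-zinc replicates 2 and 3, and to 173 without MTF1 siRNA low-zinc replicate 2. It was 117 with the replicate block. The 3 control arrays at high zinc detected 18969 to 19469 probes and the 3 MTF1 siRNA arrays 18287 to 18671. The comparisons at low and high zinc share no array. They had 2 rises and 6 falls in common, against 0.0336 and 0.147 for independent lists of those sizes, and their log2 changes correlated at r = 0.129 across all genes, which are not independent replicates. Of the 280 genes called in either, 71.8% differed in the same direction in the other.

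The interaction asks directly whether the zinc response differed between the siRNAs. Only 3 genes passed in limma. MT1B and MT1M rose less, as measured, with MTF1 siRNA, at -2.74 ± 0.17 (SE, adjusted p = 4.22e-05) and -1.78 ± 0.23 (adjusted p = 0.0381). EMP3 responded more (1.04 ± 0.14, adjusted p = 0.0381) and went from 7.88 ± 0.02 to 8.40 ± 0.08 with control siRNA and from 7.64 ± 0.10 to 9.21 ± 0.14 with MTF1 siRNA (SD, n = 3). MT1B at low zinc was not above background with either siRNA, and MT1M was detected on 1 of the 6 low-zinc arrays, so their low-zinc ends rest on the background floor. A difference between the siRNAs at low zinc could therefore not be read for these genes. Their interactions cannot tell a smaller zinc response from a lower level at both zinc concentrations. The call of MT1B held in every omission and under every alternative that gave it a value, which the strict filter did not. No omission or alternative lifts the floor, so this does not settle the question for MT1B. The calls of MT1M and EMP3 were each lost without 10 of the 12 arrays in turn (both held without MTF1 siRNA low-zinc replicate 3, EMP3 also without MTF1 siRNA high-zinc replicate 3 and MT1M also without control low-zinc replicate 3), with the replicate block, with median-centred arrays and with no filter, where adjusted p reached 0.179.

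For the other genes of zinc handling a difference in response was not shown. SLC30A1 differed by -0.49 ± 0.14 (SE; limma, adjusted p = 0.175), SLC39A10 by 0.49 ± 0.24 (0.341), MT1X by 1.21 ± 0.63 (0.366), MT2A by 0.53 ± 0.37 (0.498), MT1G by 0.47 ± 0.57 (0.716), MT1E by 0.29 ± 0.35 (0.714), and MT1H by -0.06 ± 0.39 (0.959). MT1F, at 0.21 ± 0.30, did not pass either. The sign of MT1E and MT1G turned without background correction, and that of MT1H turned with median-centred arrays. A second MT1H probe, above background on 4 of the 12 arrays, passed downward among all entering probes (adjusted p = 0.0378), and its change rests on the background floor. Next by p-value were the RNA polymerase III subunit POLR3K (0.94 ± 0.16) and SSPOP, the latter above background in 1 of the 4 groups, neither of which passed (adjusted p = 0.106 for both).

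As lists, the zinc change was shifted upward with MTF1 siRNA for immediate early genes, which rose with both siRNAs, and downward for cholesterol synthesis genes (camera, adjusted p = 0.0279 for both), each with 0 members past the threshold over all genes and 1 and 0 adjusted over the list alone. Both calls were lost with an estimated correlation (adjusted p = 0.153 for both). The metallothionein list did not pass (adjusted p = 0.474; its median, 0.25, and its mean, -0.23, differ in sign), nor did the SLC30 list (adjusted p = 0.103). With the authors' log2 values, which keep the background, both passed downward (adjusted p = 0.00662 and 0.00876). The other lists did not pass (adjusted p from 0.0756 to 0.913). The number of genes called was 117 with those values (86 upward, 31 downward) and 146 without background correction (101 upward, 45 downward). The unadjusted p was under 0.05 for 2278 genes.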

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

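The test of a shared pool of metallothionein RNA and the regrouping of siRNA labels were chosen after the results were seen; the other tests given here were planned.

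The results listed here drew attention because they passed the test of a difference in zinc response between MTF1 siRNA and control siRNA. For MT1B and MT1M the low-zinc levels lay at or near background, so that test cannot show a smaller response. The results were found among genes and lists. They were MT1B (-2.74), MT1M (-1.78) and EMP3 (1.04) among genes (log2), and among lists the immediate early genes and cholesterol synthesis (camera, adjusted p = 0.0279 for both, lost with an estimated correlation at 0.153). Of 100 drawn regroupings of the zinc labels within each siRNA, the real one included, 4 gave at least 3 genes. These regroupings left the large zinc effect in the residual, whose variance was a median 4.31 times the real one for genes changed by zinc, so the share decides nothing. The highest other count was 176, from a regrouping that kept the zinc labels of the control arrays and exchanged most of those of the MTF1 siRNA arrays. The 2 others that kept as many labels of each siRNA called 0 and 1. In such a regrouping the contrast holds the zinc effect itself, so the 176 does not measure chance. Regrouping the siRNA labels within each zinc concentration also gave 4 of 100 with at least 3 genes (highest other 64), with a median residual variance of 1.65 times the real one for genes changed by zinc and 1.30 times for all genes. Because that variance was raised and this test was chosen after the result, chance was left open as the source of the count. Groups of 3 arrays were not tested for outliers.

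The 5 metallothioneins that were bright with both siRNAs at high zinc (12.2 or more) differed less between the siRNAs there than at low zinc, as estimated, although no difference between the zinc concentrations passed. MT1X went from -1.54 at low to -0.34 at high zinc, MT2A from -0.78 to -0.25 and MT1G from -1.80 to -1.33 (interaction, lowest adjusted p of the bright probes 0.366). The pattern depends on the processing. The interaction turned negative for MT1E and MT1G without background correction (-0.055 and -0.33) and with the authors' values (-0.029 and -0.27). For MT1F it did so without MTF1 siRNA low-zinc replicate 1 (-0.033). The estimate did not shrink for MT1H (-1.49 and -1.55), which stood at 12.77 with control and 11.22 with MTF1 siRNA. Its low-zinc estimate may rest in part on the background floor. Compression of bright probes may contribute and stays open: in 15 genes with a bright and a dimmer probe, the bright probes moved 1.02 times as much with zinc (95% bootstrap interval 0.555 to 1.79; 0.648 without RNA28SN5). A single pool of metallothionein RNA read by all probes stays open with it: the differences at high zinc lay up to 2.62 apart (SE 0.289), but between a dim and a bright probe, which compression alone could part. A biological difference between metallothionein genes in their need for MTF1 stays open as well and was not tested.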

How the results depend on the processing

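All alternatives given here were planned. Without background correction, MTF1 siRNA changed 159 genes at low zinc and 977 at high zinc, and 146 interactions passed. The authors' log2 values gave 152, 942 and 117, and a mean-variance trend with robust eBayes 143, 885 and 101. The strict filter (all 12 arrays) gave 69, 540 and 1, and no value for MTF1. With no filter on dim probes, zinc with control siRNA changed 1540 genes, MTF1 siRNA 2 at low and 30 at high zinc, and 1 interaction passed. Median-centred arrays gave 7 at low zinc and 1 interaction, and all entering probes 412 at high zinc. With only the 2 groups compared, limma called 0 genes at low zinc (1955 at an unadjusted p under 0.05) and 38 at high zinc. The replicate number as a block gave 2308 and 2055 genes for zinc, 3 and 117 for MTF1 siRNA and 1 interaction. Deviations of same-numbered arrays of different groups correlated at -0.097 to 0.144 (median 0.0030, against 0.0133 for different numbers). They showed no clear pairing by number but cannot exclude it. The labels do not say whether same-numbered samples were processed together. The lower MTF1 level at high zinc (-0.98) missed the threshold with no filter (0.129), with the block (0.0825) and with only the 2 groups (0.0984). At low zinc it was -0.71 with the block (0.254). The causes of these shifts were not tested.

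Leaving out each array in turn gave 1607 to 2589 and 1555 to 2335 genes for zinc with control and MTF1 siRNA, 0 to 20 and 21 to 245 for MTF1 siRNA at low and high zinc, and 1 to 9 interactions. The MTF1 difference ran from -0.90 to -0.61 at low and from -1.24 to -0.77 at high zinc, and its zinc change with MTF1 siRNA from -0.44 to 0.032, above 0 without MTF1 siRNA low-zinc replicate 1 (0.02) or high-zinc replicate 3. The other reversals were of values that had not passed. SLC30A1 at low zinc was 0.0042 with median-centred arrays. The interactions reversed for MT1E without background correction (-0.055) and with the authors' values (-0.029), for MT1G likewise (-0.33 and -0.27), and for MT1H with median-centred arrays (0.054). Over omissions MT1F ran from -0.033 to 0.47 and MT1H from -0.35 to 0.25, and MT1H was also above 0 without control low-zinc replicate 2 (0.19) or control high-zinc replicate 3 (0.09). The SLC39 list at high zinc reversed with median-centred arrays (adjusted p = 0.997). The causes were not tested.

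Of the 43 list calls over all comparisons, where a list can count more than once, 27 missed the threshold with an estimated correlation. That of p53 targets with MTF1 siRNA also missed it with the block. Among called named genes, 5993 comparisons with an alternative kept direction and call and 889 kept the direction alone. Background limits dim genes, whose folds are bounds. No chip or position is given in the sources used here, so blocking on it was not run.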

Other observations

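The tests of shared changes at both zinc concentrations, of a single array and of the small RNAs were chosen after their results were seen; the counts over other splits of the arrays were planned.

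Structured non-coding RNAs, most of them small and made by RNA polymerase III or part of the splicing machinery, rose with zinc. Of 23 measured, 21 rose with each siRNA, by a median of 1.24 with control and 1.45 with MTF1 siRNA (log2; 1.37 for the latter with RNAs not above background in 1 group set to their bounds). Without the long 18S and 28S ribosomal RNAs, 20 and 19 of 21 rose. Singled out after their values were seen, with control siRNA these were 5S ribosomal RNA RNA5S9 (3.38), RN7SK, which restrains transcription elongation (3.11), RPPH1 of RNase P (3.01) and the long 28S ribosomal RNA RNA28SN5 (2.55, with a dimmer probe at 1.07). All 12 small nuclear RNAs rose, among them RNU6ATAC (1.77) and RNU4-2 (1.78), and so did the 3 copies of U3, SNORD3A, SNORD3C and SNORD3D, by a median of 4.07 and 4.30. RNY3 (0.08, adjusted p = 0.827) did not pass. With MTF1 siRNA against control, 0 of the 23 passed at either zinc concentration by limma. Copies of RNU1, RNU4 and SNORD3 are near-identical, so their probes are not separate measurements.

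The rise was seen with the other scalings: with median-centred arrays 20 and 21 of 23 rose, and without background correction and with the authors' values 21 and 20, by medians between 0.74 and 1.48. An equal gain in the recovery of small RNAs of every kind was argued against. The 95 other small nucleolar and Cajal body RNAs had a median change 0.0416 of that of the structured RNAs (95% bootstrap interval -0.0073 to 0.0725, or -0.0111 to 0.0718 without the 18S and 28S RNAs). Of these 95, 8 rose and 3 fell with control siRNA, and 14 rose and 1 fell with MTF1 siRNA. They exclude U3, left out after its rise was seen, and were not matched in level. A better recovery of some small RNAs therefore stays open. The structured RNAs rose beyond the 6584 genes of the same brightness, whose median change was -0.0193 of theirs. Quantile normalization gives all arrays the same distribution, which holds the median of so large a set near 0. The ratio therefore does not test a rise of all probes of that brightness before normalization. A change in the processing or tailing of these RNAs, or in their level, may lie behind the pattern and was not tested.

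MTF1 siRNA changed more genes at high than at low zinc (271 and 17). A single array as the whole source was argued against, since without any 1 of the 12 arrays the count at high zinc, at least 21, stayed above that at low zinc. The gap narrowed much, to 21 against 9 genes without MTF1 siRNA high-zinc replicate 2 and 39 against 9 without its replicate 1. Without control high-zinc replicate 3 it was 45 against 8. How far single arrays widen the gap was left open. Whether the same changes were present at low zinc and missed there was left open: the median change at low zinc was 0.251 of that at high zinc (95% bootstrap interval 0.181 to 0.345), and 72.7% of the 271 genes had the same sign. These genes were chosen by their call at high zinc, which tends to raise the high-zinc median and lower the ratio. The interval does not cover this. The biological difference that the design names, a need for MTF1 that grows with zinc, stays open and was not tested further.

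For comparisons of 3 against 3 arrays, the 10 splits are too few for a share under 0.05. In each of the 4 comparisons only 1 split, the real one, gave as many genes, with 2573, 2244, 17 and 271 genes against a highest other count of 0, 0, 1 and 1. Every other split mixes the 2 groups compared, which leaves their difference in the residual and lowers its count. These lower counts therefore decide nothing.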
